A study of Homo sapiens with 2 samples.

How the data were processed

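Samples were 2 two-colour Agilent arrays of 293FT cells. Per the labels' protocols, cytosolic extracts were separated on sucrose gradients of 10 to 50%, fractions with more than 3 ribosomes were pooled, RNA was immunoprecipitated with an antibody against CBP80 or eIF4E and extracted with Trizol, and labelled cRNA was made by linear amplification with an Agilent low-input kit. Per the labels, the CBP80 IP carried Cy3 and the eIF4E IP Cy5 on both arrays, so a dye effect of a probe cannot be separated from a difference between the IPs. The arrays are called biological replicates, no further detail of their origin is given in the sources used here, and the p-values measure only the spread between these samples. Both arrays lay on 1 slide and were scanned together, so no batch could be tested.

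The deposited scanner files hold, per the file headers, spot intensities from Agilent Feature Extraction 10.7.3.1 with probe coordinates on hg18. The mean spot intensity and the local background intensity are raw, per the file headers. The processed intensities were background-subtracted with spatial detrending and dye-normalized (linear and LOWESS), per the file headers. The deposited log10 ratio is red over green, that is eIF4E IP over CBP80 IP, per the file headers and the dyes in the labels. The authors' value table holds log2 values of unstated normalization. Set against the scanner's log ratio turned to red over green, its columns had correlations of −1.00 and slopes of −1.00 with intercepts of −0.0655 and −0.0545, so its direction is CBP80 IP over eIF4E IP. Its medians were −0.0437 and −0.0439, its exact centring and filter remain unknown, and it was used as an alternative.

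Mean intensities were corrected with the local median background by normexp with an offset of 50 (limma 3.58.1, R 4.3.3), fitted on all spots, and normalized within each array by loess, with control and outlier spots given weight 0. No scaling between arrays was applied. The offset pulls the ratios of dim probes toward 0. Spots of a probe were averaged, and a gene was represented by its brightest probe over both channels and arrays. A probe was tested if at least a share of 0.5 of its spots was well above background in the same channel on both arrays. A ratio of a gene above background in one channel alone is measured against a level near background, and no such gene is named. Median intensities of the negative controls were 54.0 and 52.1 in Cy3 and 45.1 and 45.8 in Cy5. The spike-in probes had medians of 55.8 and 55.0 in Cy3 and 47.3 and 47.8 in Cy5, so they gave no external scale. The number of arrays limits the precision: the SE of a gene's mean log2 ratio was 0.0764 after pooling, and the smallest ratio called was 0.17 on the log2 scale.

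Symbols were updated through a RefSeq gene table of another build, used for names alone: of 34127 probes, 24827 were matched by accession, 1276 by symbol and 500 by synonym, and 7524 kept the file's name. No hg18 annotation was used here, so exons and untranslated regions are not given.

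The mean log2 ratio was tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each ratio pairs the channels of an array. Genes of 2-fold or more on each array were counted without a test. Lists of genes with at least 5 tested members were tested with camera at a correlation of 0.01, adjusted over the lists. The 25 lists were replication-dependent histones, ribosomal proteins, other translation factors with 5′ terminal oligopyrimidine tracts, targets of nonsense-mediated decay, small nucleolar RNA hosts, integrated stress response, endoplasmic reticulum chaperones, mRNAs sensitive to eIF4E, immediate early genes, single-exon genes, zinc finger genes, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes (no member found by name), mitochondrial ribosome, proteasome, cytosolic chaperones, splicing factors, selenoproteins, cap-binding factors, nuclear long noncoding RNAs, mitosis, DNA replication, cholesterol synthesis and tissue-restricted markers.

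The genes named were fixed by a rule before the data were examined: the 12 highest and 12 lowest mean ratios among called genes of one sign on both arrays, above background in both channels, unsaturated and with a regular symbol; up to 4 members of each list with the largest absolute ratio; and every tested cap-binding factor. A few genes that met this rule are not reported here. The text says where other genes were named after their values were seen.

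The procedure was tested on simulated intensities of the 16706 genes. Of genes changed by 0.5 on the log2 scale, 73.1% were recovered with the right sign (median estimate 0.343), and 100% of those changed by 1 or 2 (median estimates 0.791 and 1.47, shrunk by the offset). Of 16466 unchanged genes, 2 were called. The simulation held no dye effect of single probes and no disagreement between probes of a gene, so it says nothing about false calls from these. It also gave every gene noise of the same setting, which suits a pooled variance. False calls among genes of wider spread, such as RN7SL1 (SD 1.30), were thus not measured.

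Alternatives were no background correction, plain subtraction, Agilent's processed signals with median centring, normexp with median centring, scaling between arrays, the authors' values, no filter or a stricter one, the mean over a gene's probes, a trended robust prior, the channels as 4 unpaired samples, a correction for probe GC content, leaving out each replicate, a 1.5-fold threshold, an estimated correlation and fry. Alternatives based on other choices of probes were added after seeing the data.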

Results

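The series measured which mRNAs in translating polysomes of 293FT cells, a human cell line derived from HEK293 cells, were bound by the cap-binding protein CBP80 and which by the cap-binding protein eIF4E. CBP80 belongs to the complex that binds the 5′ cap of newly made transcripts in the nucleus, and eIF4E binds the cap of cytoplasmic mRNAs during translation. Polysome fractions with more than 3 ribosomes were pooled from sucrose gradients, and RNA was immunoprecipitated (IP) with an antibody against one of these proteins. Each of 2 arrays, described in the labels as biological replicates, carried RNA of the CBP80 IP labelled with Cy3 and RNA of the eIF4E IP labelled with Cy5. All ratios below are log2 CBP80 IP over eIF4E IP, so a positive value is a higher signal in the CBP80 IP. Neither an input sample nor a dye swap was analysed here, so the ratio sets one IP against the other and contains any dye effect of a probe. How far the labelling of RNAs without a poly(A) tail follows their amount was not tested. Fold differences of such RNAs are thus differences in array signal.

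On array 1, 57.3% of the 43118 noncontrol spots were well above background for the CBP80 IP and 65.1% for the eIF4E IP. On array 2 these shares were 61.2% and 64.1%. Levels of 18318 probes above background in every channel correlated at r = 0.996 between the CBP80 IPs of both replicates and at r = 0.998 between the eIF4E IPs. Between the CBP80 IP and the eIF4E IP of one array, r was 0.962 in replicate 1 and 0.969 in replicate 2 (correlations across probes, which are not independent replicates). Of 16706 genes tested, 14814 were above background in both IPs, 1744 in the eIF4E IP alone and 148 in the CBP80 IP alone.

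The first question was which transcripts differed between the IPs. The highest ratios toward the CBP80 IP belonged to small noncoding RNAs and replication-dependent histone genes. RNU2-2, a U2 small nuclear RNA gene of the spliceosome, was 16.6-fold higher in the CBP80 IP (log2 4.06 ± 0.05, SD, n = 2). RPPH1, the RNA subunit of ribonuclease P, was 14.8-fold higher (log2 3.89 ± 0.25, SD, n = 2). RNVU1-18, a U1 small nuclear RNA variant named RNU1-5 on the array, had a log2 ratio of 2.80 ± 0.04 (SD, n = 2). RN7SL1, the RNA of the signal recognition particle, had a log2 ratio of 3.89 on array 1 and 2.06 on array 2, a spread (SD 1.30) far wider than that of the other genes named here. The remaining 8 of the 12 highest named genes encode core histones H2A, H2B and H4. H2AC20 (HIST2H2AC on the array) was 10.5-fold higher in the CBP80 IP (log2 3.39 ± 0.25, SD, n = 2) and its neighbour H2AC21 9.53-fold (log2 3.25 ± 0.21, SD, n = 2). Their probes lie at bases 148125487 to 148125546 and 148125809 to 148125868 of chromosome 1 (hg18). H4C5, H2BC5, H2AC4, H4C9, H4C8 and H4C12 followed, with log2 ratios down to 2.77 for H4C12 (other probe 1.60).

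**Figure D1:**
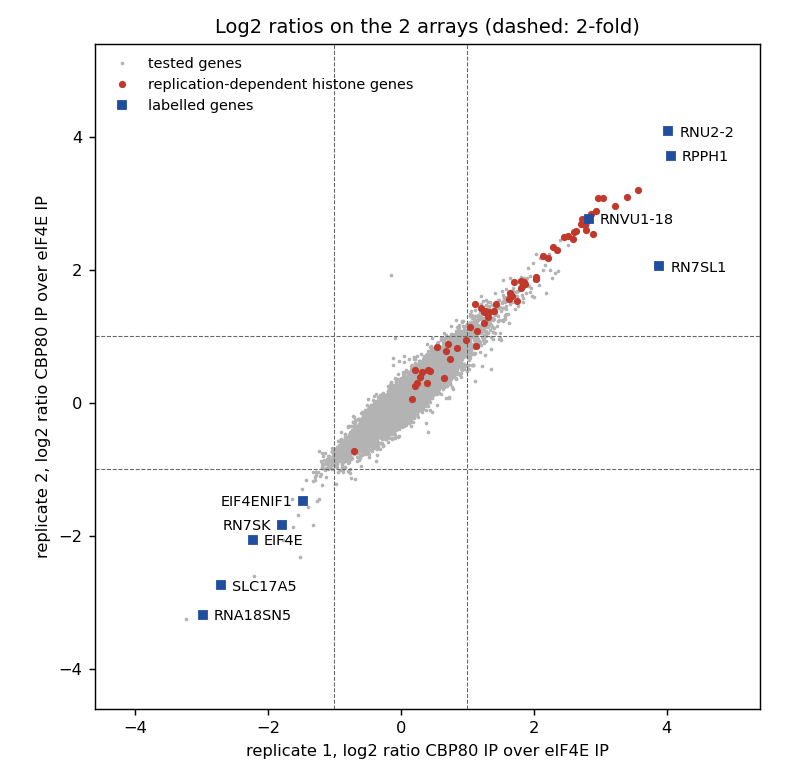
Log2 ratio of CBP80 IP over eIF4E IP on replicate 2 (y axis) against replicate 1 (x axis) for the 16706 tested genes, 1 point per gene. Dashed lines mark 2-fold, the replication-dependent histone genes lie mostly in the upper right, and EIF4E (log2 −2.22 and −2.06) lies in the lower left.

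Toward the eIF4E IP, the largest ratio among genes with a regular symbol and above background in both IPs belonged to RNA18SN5, a gene of the 18S ribosomal RNA, which was 8.47-fold higher in the eIF4E IP (log2 −3.08 ± 0.14, SD, n = 2). EIF4E, which encodes the precipitated protein itself, was 4.42-fold higher (log2 −2.14 ± 0.11, SD, n = 2), and all 3 of its probes on chromosome 4 gave ratios between −2.14 and −1.34. EIF4ENIF1, which encodes the eIF4E transporter 4E-T, was 2.77-fold higher in the eIF4E IP (log2 −1.47) at its brightest probe and had a ratio of −0.77 at its other probe. SLC17A5, which encodes the lysosomal sialic acid transporter, had a ratio of −2.73 at bases 74360003 to 74360062 of chromosome 6 (hg18). Its other probe, a dim one (mean log2 intensity 6.63), gave 0.17. RN7SK, the 7SK small nuclear RNA, had a ratio of −1.80 ± 0.03 (SD, n = 2). The others of the 12 lowest were DYTN at −1.92, AGTRAP at −1.91 (−1.51 and −2.31 on the arrays), C3AR1 at −1.58, the actin-severing factor DSTN at −1.54, PANX2 at −1.48 (its other probe was not above background in both IPs), ENOPH1 at −1.39 and TOMM20L at −1.34. The largest adjusted p among these 24 genes was 3.48e-66 (limma, Benjamini-Hochberg). The variance was pooled fully, so every gene had the same SE of 0.0764 and its own spread between the arrays did not enter its p. These p-values thus reflect the size of the mean ratio alone and do not allow for a dye effect.

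Across all genes, limma called 9486 of 16706 (56.8%) at an adjusted p under 0.05, 4862 of them higher in the CBP80 IP and 4624 higher in the eIF4E IP. Most of these differences were small, and 79.1% of the called genes had a mean difference under 1.5-fold. A difference of 2-fold or more on each array separately was found for 363 genes, of which 332 (91.5%) were higher in the CBP80 IP and 31 higher in the eIF4E IP. The latter count was 85 on array 1 alone, that is without replicate 2. Differences of 4-fold or more were found for 33 and 5 genes. The log2 ratios correlated between the arrays at r = 0.934 (Spearman rho = 0.891, across genes, which are not independent replicates), and 84.4% of the genes had one sign on both arrays. The p-values measure only the typical spread between these 2 arrays on a single slide, with the variance pooled fully over all genes. A gene's own spread, which has 1 residual degree of freedom, did not enter them. The split between the directions depended on how background and scaling were treated: the deposited log2 ratios, of unstated normalization, gave 764 genes 2-fold higher in the CBP80 IP and 609 in the eIF4E IP, and median centring in place of loess gave 49 and 1051.

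Of 25 gene lists fixed before the data were examined, 24 had enough tested genes, and 7 passed an adjusted p under 0.05 in limma's camera test with a preset correlation of 0.01 between genes. With an estimated correlation, where the test rests on 1 residual degree of freedom, camera called 0 lists and 1 had an unadjusted p under 0.05. The estimate was 0.0046 for histones and 0 for small nucleolar RNA hosts, below the preset 0.01. A higher correlation thus did not cost these lists their call. Among the 7 lists it exceeded 0.01 for splicing factors (0.098), cytosolic chaperones (0.059) and DNA replication (0.054). With so few degrees of freedom this setting can hardly call a list, so its p-values do not decide whether correlation matters. Limma's fry, which tests a list against no change and not against the other genes, called 2 (histones and small nucleolar RNA hosts).

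The replication-dependent histone genes, whose mRNAs are made in S phase and mostly end in a stem-loop without a poly(A) tail, shifted most. Of 63 tested genes, 61 were higher in the CBP80 IP, 1 was lower and 1 did not pass, with the same counts adjusted over the list alone. The median log2 ratio was 1.64 (3.12-fold; medians of 1.67 and 1.60 on the arrays), and 45 of the 63 were 2-fold higher on both arrays. All histone families took part, with medians of 2.55 over 14 H4 genes, 1.97 over 17 H2B genes, 1.64 over 15 H2A genes, 1.09 over 13 H3 genes and 0.98 over 4 H1 genes. The lower gene was H4C13 (log2 −0.71) and the gene that did not pass was H4C3 (0.12, limma adjusted p = 0.18), both named after their values were seen. The camera adjusted p was 5.57e-136 with the preset correlation, and the adjusted p = 0.54 with an estimated correlation. Histone genes are near-identical in sequence, so values of single members are uncertain because probes can cross-hybridise. The labelling of mRNAs without a poly(A) tail was not tested, so the shift of the list is one of array signal.

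Host genes of small nucleolar RNAs also had higher ratios toward the CBP80 IP, with 14 of 16 higher and 2 lower, also adjusted over the list alone. The median log2 ratio was 0.47 (camera adjusted p = 0.000892; adjusted p = 0.755 with an estimated correlation), and with median centring in place of loess it was −0.24 (camera adjusted p = 0.398), where all tested genes had a median of −0.334. SNHG9 had a ratio of 1.32 ± 0.10, SNHG8 of 1.14 ± 0.02, SNHG5 of 1.01 ± 0.08 and ZFAS1 of 0.86 ± 0.07 (SD, n = 2 each). Of 34 genes for SR proteins, hnRNPs and other splicing factors, 19 were higher in the CBP80 IP, 8 lower and 7 did not pass, also adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.00167; adjusted p = 0.755 with an estimated correlation). The camera adjusted p was 0.0749 with Agilent's processed signals, 0.0993 with the most downstream probe of each gene, an alternative chosen after seeing the data, and 0.953 with median centring, which turned the median to −0.45. HNRNPA2B1 had the highest ratio of this list at 2.44 ± 0.10 (SD, n = 2), but its other probes gave 0.34 and 0.10, the latter at a dim probe (mean log2 intensity 6.28). RBM39 (1.23, other probes 0.38 and 0.42), HNRNPU (1.14, other probe 0.62) and SF3B1 (1.10) followed. Of 8 nuclear long noncoding RNAs, 5 were higher in the CBP80 IP (6 adjusted over the list alone) none was lower and 3 did not pass. The median was 0.21 (camera adjusted p = 0.011; adjusted p = 0.755 with an estimated correlation), and −0.13 with median centring (camera adjusted p = 0.101). MALAT1, a nuclear speckle RNA, had a ratio of 1.41 ± 0.15 and NEAT1, the paraspeckle scaffold RNA, of 1.01 ± 0.07 (SD, n = 2 each). TUG1 (0.59) and PVT1 (0.22) were higher by less and turned to −0.22 and −0.02 with median centring.

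**Figure D2:**
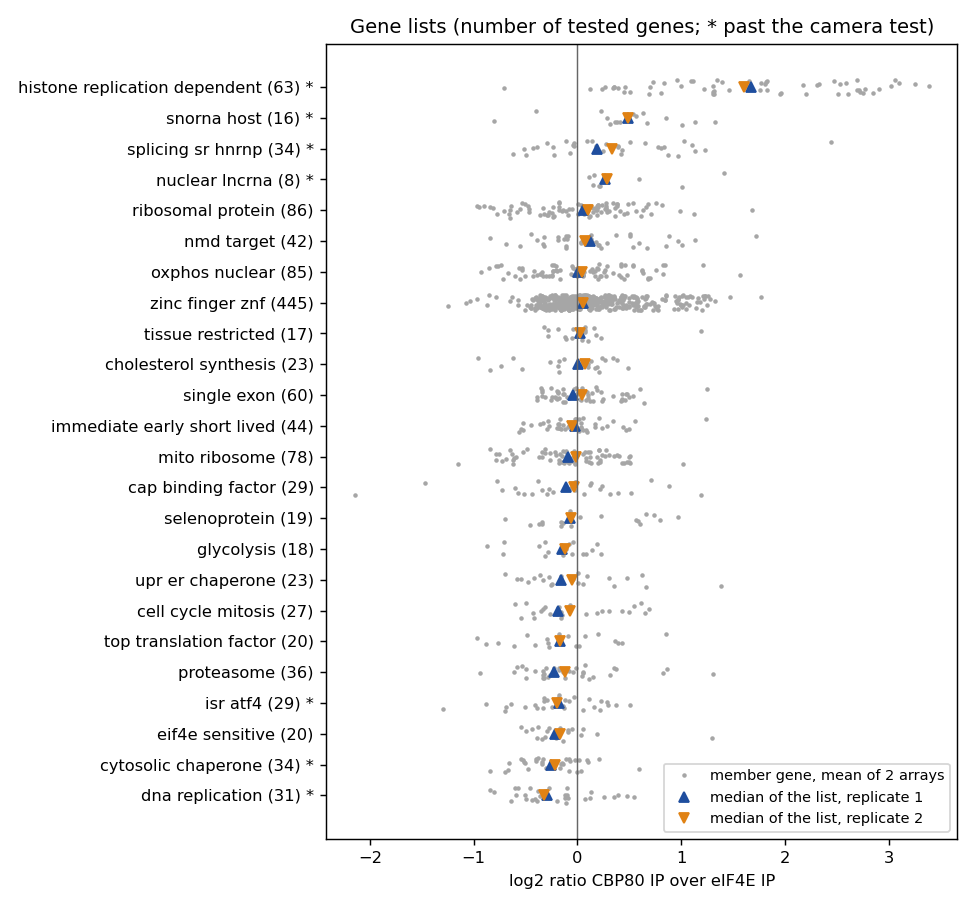
Log2 ratio of CBP80 IP over eIF4E IP (x axis) for the tested members of 24 gene lists (y axis, number of tested genes in parentheses), with grey points for the genes and triangles for the list's median on each array. The histone list, with a median of 1.64, stands apart from the other lists, whose medians lie between −0.28 and 0.47, and stars mark the 7 lists past the camera test with the preset correlation.

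Genes of the remaining 3 called lists had higher ratios toward the eIF4E IP. Of 34 cytosolic chaperone and chaperonin genes, 19 were higher in the eIF4E IP, 2 higher in the CBP80 IP and 13 did not pass, also adjusted over the list alone. The median log2 ratio was −0.23 (camera adjusted p = 0.00249; adjusted p = 0.755 with an estimated correlation). HSPD1, the mitochondrial chaperonin (log2 −0.84 ± 0.08, SD, n = 2), CCT4, a subunit of the cytosolic chaperonin (−0.70 and −0.69 at its probes), and the cochaperone BAG2 (−0.66) led the list. HSP90AA1 had −0.67 at its brightest probe and 0.16 and 0.74 at the others. Of 31 DNA replication genes, 17 were higher in the eIF4E IP, 5 in the CBP80 IP and 9 did not pass, also adjusted over the list alone. The median was −0.28 (camera adjusted p = 0.011; adjusted p = 0.755 with an estimated correlation). GINS2 of the replicative helicase (−0.84), the single-strand binding protein RPA1 (−0.81, other probe −0.21), the origin recognition subunit ORC6 (−0.64) and the clamp loader RFC5 (−0.60) had the lowest ratios. This list's camera adjusted p was 0.0749 with Agilent's processed signals, 0.0517 in the authors' values and 0.0719 with the most downstream probes. Of 29 genes of the integrated stress response, 15 were higher in the eIF4E IP, 6 in the CBP80 IP (15 and 7 adjusted over the list alone) and 8 did not pass. The median was −0.18 (camera adjusted p = 0.0215; adjusted p = 0.755 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, had the lowest ratio of the list at −1.30 ± 0.19 (SD, n = 2), followed by the methionyl-tRNA synthetase gene MARS1 (−0.88, other probe 0.32), DDIT4 (−0.69) and TRIB3 (−0.69). The camera adjusted p of this list was 0.12 with plain background subtraction, 0.117 in the authors' values and 0.169 with Agilent's processed signals.

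The other 17 lists did not pass the camera test. Ribosomal protein genes went both ways, with 39 of 86 higher in the CBP80 IP and 32 lower. Their median was 0.12 (0.06 on array 1 alone, that is without replicate 2, and 0.10 on array 2 alone) and their mean 0.03, while the test's direction was downward (adjusted p = 0.92). RPL39 was higher at all 4 probes (1.11 to 1.41) and RPS3A lower at all 5 (−0.75 to −0.66 at its unsaturated probes, while the probe used for the gene was saturated). RPS29 had 1.69 at its brightest probe and 1.80 and 1.87 at others. Its most downstream probe, far dimmer (mean log2 intensity 7.69 against 15.35), gave −0.38. Genes of mRNAs reported as targets of nonsense-mediated decay had a median of 0.10, with 17 of 42 higher in the CBP80 IP and 10 lower (camera adjusted p = 0.17). Among them SMG1, a kinase of that pathway, had 1.72 at its brightest probe. Its 6 probes gave 1.41 to 2.35, except the most downstream, a dim one at −0.00060 (mean log2 intensity 7.19). RBM3 had 0.97 and 1.62. Genes of mRNAs reported as sensitive to eIF4E had a median of −0.20, with 12 of 20 higher in the eIF4E IP and 2 in the CBP80 IP (camera adjusted p = 0.13, and 0.0326 in the authors' values). NBN (−0.54), RRM1 (−0.50) and ODC1 (−0.44) were among the lower ones. VEGFA had 1.30 at its brighter probe and −0.11 at a dim one (mean log2 intensity 6.85). Zinc finger genes, with 168 of 445 higher in the CBP80 IP and 107 lower, had a median of 0.04 (camera adjusted p = 0.081). ZNF625 reached 1.77 at its brightest probe but 0.17 at the other, which was dim (mean log2 intensity 6.18).

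Medians of 5 lists lay between −0.18 and −0.12. Of translation factor genes, 5 of 20 were higher in the CBP80 IP and 10 in the eIF4E IP, of proteasome genes 6 and 19 of 36, of glycolysis genes 2 and 7 of 18, of endoplasmic reticulum chaperone genes 6 and 10 of 23, and of mitosis genes 9 and 12 of 27. On array 2 alone, that is without replicate 1, the medians were nearer 0 for the endoplasmic reticulum chaperone list (−0.06, against −0.15 on array 1 alone) and the mitosis list (−0.07, against −0.18). Medians of 6 others lay between −0.06 and 0.04. Of mitochondrial ribosome genes, 21 of 78 were higher in the CBP80 IP and 27 in the eIF4E IP, of selenoprotein genes 8 and 5 of 19, of immediate early genes 11 and 16 of 44, of single-exon genes 18 and 17 of 60, of cholesterol synthesis genes 8 and 9 of 23, and of nuclear oxidative phosphorylation genes 33 and 31 of 85, whose median of 0.04 turned to −0.763 with median centring. On array 1 alone and array 2 alone, the medians were −0.09 and −0.02 for the mitochondrial ribosome list, −0.03 and −0.06 for the immediate early list, −0.05 and 0.04 for the single-exon list, 0.01 and 0.08 for the cholesterol list and 0.01 and 0.04 for the oxidative phosphorylation list. The camera adjusted p of these 11 lists ranged from 0.080 to 0.97. The selenoprotein list had a median of −0.06, a mean of 0.13 and an upward test, and the cholesterol list a median of 0.04, a mean of −0.08 and a downward test. Adjusted over the list alone, the counts were those given for all but the mitosis (9 and 14), selenoprotein (8 and 6), oxidative phosphorylation (34 and 33) and zinc finger lists (168 and 108). Several members of these lists passed singly. COX8A, a cytochrome oxidase subunit, had a ratio of 1.56, the proteasome subunit gene PSMB4 of 1.31, the signalling GTPase gene RHOB of 1.25 (0.22 at its other probe) and the transcription regulator ID1 of 1.24. MRPS35 of the mitochondrial ribosome had −1.15, the translation-associated NACA −0.97, the glucose transporter SLC2A1 −0.87 and the sterol synthesis gene IDI1 −0.84. Of 44 markers of other tissues on the array, 17 were tested. They had a median of 0.04 (0.0246 and 0.0251 on the arrays), with 3 higher in the CBP80 IP, 4 lower and 10 that did not pass.

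Among 29 genes for cap-binding proteins and their partners, 8 were higher in the CBP80 IP, 13 were higher in the eIF4E IP and 8 did not pass, also adjusted over the list alone (median log2 −0.06, and −0.11 and −0.03 on the arrays; camera adjusted p = 0.081). NCBP1, which encodes CBP80, had a ratio of −0.29 ± 0.03 and NCBP2, which encodes its partner CBP20, of −0.77 ± 0.07 (SD, n = 2 each), so both were higher in the eIF4E IP. Other transcripts higher in the eIF4E IP were EIF4E and EIF4ENIF1 (above), the scaffold gene EIF4G1 (−0.72), EIF4A1 (−0.60, with 0.94 at its most upstream probe), EIF4G2 (−0.57, other probe 0.37), the stem-loop binding protein SLBP (−0.51), EIF4EBP1 (−0.44), EIF4A2 (−0.38), KPNA2 (−0.35), MIF4GD (−0.27) and EIF2S1 (−0.23). Ratios on array 1 alone and array 2 alone were −0.43 and −0.03 for EIF2S1, −0.53 and −0.22 for EIF4A2 and −0.28 and −0.60 for EIF4EBP1. Of the nonsense-mediated decay factors, UPF3A (1.19) and UPF2 (0.89, with 0.46 to 1.11 over 5 probes) were higher in the CBP80 IP, while UPF1 (0.12) and UPF3B (0.13) did not pass and were below 0 with median centring. EIF4EBP2 (0.71, other probe −0.07), PABPN1 (0.52), PABPC1 (0.39), CTIF (0.31), NCBP3 (0.24) and EIF3G (0.22) were higher in the CBP80 IP and below 0 with median centring, where all tested genes had a median of −0.334. Here too the arrays differed, with 0.48 on array 1 alone and 0.14 on array 2 alone for CTIF, 0.10 and 0.38 for NCBP3 and 0.34 and 0.11 for EIF3G. No difference was called for EIF4E2 (−0.02), EIF4E3 (0.06), EIF4A3 (−0.03), EIF4G3 (−0.08, other probe 1.09), KPNB1 (−0.02, other probe −0.34) or PHAX (−0.06).

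Probes of one gene often differed by more than the arrays did. In 2671 genes with several mRNA probes above background, the ratios of the most upstream and the most downstream probe correlated at r = 0.346 across genes, whereas the ratio of the upstream probe correlated at r = 0.943 between the arrays. The upstream probe had the higher ratio toward the CBP80 IP in 75% of the genes, by a mean of 0.334 ± 0.010 (SE, n = 2671 genes). The 6 probes of EEF1A1, which encodes the translation elongation factor eEF1A, gave −1.16, −0.77, −0.14, 0.21, 0.71 and 1.19 from the most downstream to the most upstream, between bases 74284045 and 74286360 of chromosome 6 (hg18), though this gene has near-identical copies. Of the 118 genes with several tested probes among the 332 higher by 2-fold in the CBP80 IP, 20 met that size at every probe. They include 5 histone genes, RPL39, the cold-shock domain genes YBX1 (1.93) and YBX3 (1.34), the chromatin remodeller HELLS (2.13), the p53 regulator MDM4 (2.42) and the long noncoding RNA NORAD (1.32), named after their values were seen. Toward the eIF4E IP, EIF4E was the single gene of 7 that met it at every probe.

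**Figure D3:**
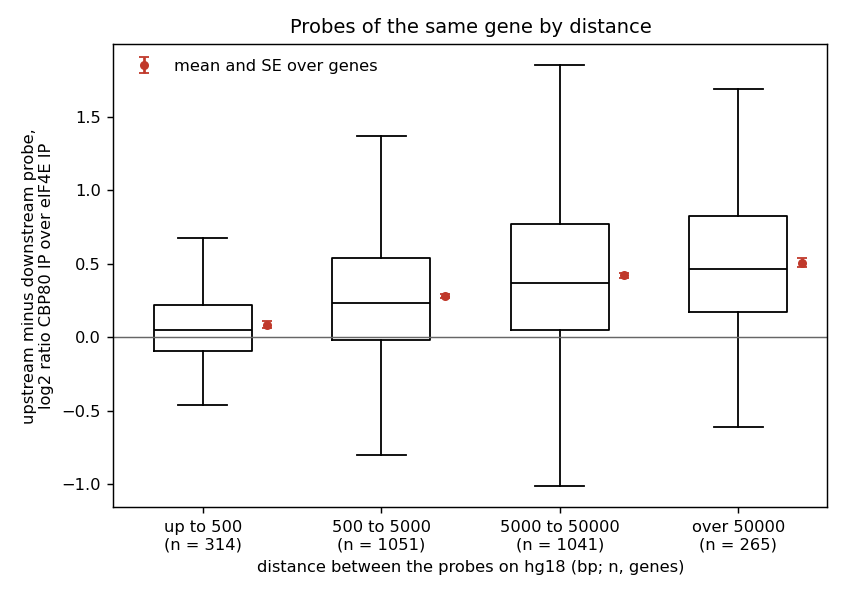
Difference in log2 ratio (CBP80 IP over eIF4E IP) between the most upstream and the most downstream probe of a gene (y axis) by their genomic distance in bp (x axis), over 2671 genes. Boxes give quartiles and medians, whiskers reach the last value within 1.5 box lengths, outliers are not drawn, and red points with SE bars give means, which rise from 0.0866 for probes up to 500 bp apart to 0.508 for those over 50000 bp apart.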

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

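The alternatives that used other choices of a gene's probes (the 2 brightest as replicates, the most downstream, every probe) were chosen after the results were seen. The count of called genes (9486) stayed between 7643 and 10083 under the other alternatives with a test, including 7909 with no pairing of channels (no replicate block). With the 2 brightest probes as replicates, limma called 0 of 3401 genes and 337 had an unadjusted p under 0.05; fewer genes were tested and probes disagree more than arrays. A single array leaves no residual degrees of freedom, so leaving out a replicate gives values without a test. The median moved by more than the spread between the arrays for 7 lists without replicate 1 and for 9 without replicate 2. Scaling between arrays by mean intensity leaves the ratios as they are and says nothing about stability. Signal over background limits the comparison of dim genes, 1744 of which were measured above background in the eIF4E IP alone.

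The number of 2-fold genes depended on background and scaling, on the threshold and on the probes required. In total, toward the CBP80 IP and toward the eIF4E IP it was 784, 633 and 151 with plain subtraction, 1358, 766 and 592 with Agilent's processed signals, 1100, 49 and 1051 with normexp and median centring, and 1373, 764 and 609 in the authors' values, against 363, 332 and 31. It was 1572, 1106 and 466 at 1.5-fold, where the lower threshold is the cause, and 21, 20 and 1 when every probe of a gene had to pass, where fewer genes could. With 1 array left out it was 440 to 508 in total, 399 to 423 toward the CBP80 IP and 41 to 85 toward the eIF4E IP, 85 without replicate 2. With the most downstream probe it was 286, 253 and 33. The correlation of the arrays was 0.870 to 0.942. The median of all tested genes moved to −0.334 with median centring, −0.113 with Agilent's signals and −0.109 in the authors' values, and the share of calls higher in the CBP80 IP went from 51.3% to 10.2%, 39.6% and 39.5%. The cause was not tested.

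The number of lists past the camera test (7) was 4 with Agilent's signals, 15 with median centring, 13 with no filter, 0 with an estimated correlation (1 residual degree of freedom), and 5 to 8 otherwise. The fry test sets a list against no change and not against the other genes, so it answers another question. It called 2 lists (histones, fry adjusted p = 0.0398, and small nucleolar RNA hosts, fry adjusted p = 0.00822). The histone list had a median of 0.93 with median centring and 1.44 with the most downstream probes, and passed camera under each setting with the preset correlation. With median centring the nuclear oxidative phosphorylation list turned from 0.04 to −0.763, and 16 named genes fell below 0: EIF3G (−0.597), UPF1 (−0.646), PABPC1 (−0.345), UPF3B (−0.301), PABPN1 (−0.299), TUG1 (−0.222), NCBP3 (−0.193), UBE2C (−0.175), SEC61G (−0.170), EIF4EBP2 (−0.127), CTIF (−0.118), SELENOW (−0.0925), DNAJC3 (−0.0912), MKI67 (−0.0555), KIF11 (−0.0303) and PVT1 (−0.024). Of these genes, all but EIF3G, UPF1 and PABPC1 stayed above −0.334, the median of all tested genes with median centring. The change was not the same for every gene: PVT1 (mean log2 intensity 6.95) went from 0.22 to −0.024 and EIF3G (9.77) from 0.22 to −0.597. Both settings share the background correction and differ in whether a trend of the ratio with intensity is removed. A gene's change thus depends on its intensity. With the mean over probes EEF1A1 turned to 0.00568, HSP90AA1 to 0.0782 and EIF4G3 to 0.505. With the most downstream probe RPS29 turned to −0.381, VEGFA to −0.114, MKI67 to −0.0952 (at a probe not above background in both IPs, so the reversal has little weight), EIF4EBP2 to −0.0667, SMG1 to −0.00060 and CANX to −0.00011, since these probes differ from the brightest ones. With median centring, the fall of EIF3G, UPF1, PABPC1 and the oxidative phosphorylation list below the median of all tested genes comes from the same difference between settings. The cause of the reversals with the mean over probes was not tested.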

Other observations

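The tests of EIF4E at single probes, of the antibodies' own targets, of eIF4E-binding proteins, of a missing poly(A) tail, of nuclear RNA, of RNA without a cap and of probe sequence as the whole cause were chosen after the results were seen, as were the gene lists of this part and the genes named from them. Small structured noncoding RNAs were mostly higher in the CBP80 IP. Of 33 tested, 23 were called higher, 1 lower and 9 did not pass, with a median log2 ratio of 0.28. Next to U1, U2, 7SL and ribonuclease P RNA, RMRP, the RNA of ribonuclease MRP, had a ratio of 2.14 ± 0.26 (SD, n = 2). Of 15 small nucleolar RNAs among them, 10 were called higher and 5 did not pass, with a median of 0.28, and the highest were SNORD3B-1 (U3) at 0.90 (other probe 1.78) and SNORA73B at 0.80. RNU12 of the minor spliceosome had 0.79, the telomerase RNA TERC 0.57 and RNU4ATAC 0.21. The RNA called lower was 7SK RNA (RN7SK, −1.80).

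All 5 tested probes on the mitochondrial genome were higher in the CBP80 IP on both arrays, although transcripts of mitochondria carry no cap. The probe starting at base 4914 (hg18) had ratios of 2.13 and 2.00, that at 13887 of 2.00 and 1.85, that at 15588 of 1.19 and 1.08, that at 14449 of 0.88 and 0.99, and that at 3369 of 0.76 and 0.73. Of 667 probes for RefSeq noncoding RNAs, 5.25% were 2-fold higher in the CBP80 IP, against 2.37% of 15155 probes for RefSeq mRNAs, with median ratios of 0.13 and 0.01. The higher median was not particular to noncoding RNAs. Probes for Ensembl transcripts, RefSeq models and cDNA or EST sequences, and probes given no transcript identifier, had medians of 0.11 to 0.13, with 1.96% to 3.86% of them 2-fold higher in the CBP80 IP. Of 11 tested replication-independent histone genes, whose mRNAs carry a poly(A) tail, 4 were higher in the CBP80 IP and 5 in the eIF4E IP, such as H2AZ1 (−0.64) and H2AZ2 (−0.78, other probe 0.44). Of 9 genes for CBP80 itself and proteins that bind its complex, 3 were higher and 3, NCBP1 among them, lower, with ZC3H18 at 0.42 (0.58 on array 1 alone and 0.26 on array 2 alone; other probe −0.22) and ALYREF at −0.74.

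Probes of one gene disagreed, and the upstream probe had the higher ratio in 75% of 2671 genes. Probe GC content is argued against, since correcting for it changed the correlation between probes by 0.00839, and probe sequence as the whole cause is argued against by the agreement of near probes: in 244 pairs up to 500 bp apart that share no stretch of 15 bases, the lower 95% bound of r (0.519) exceeded the upper bound of pairs over 50000 bp apart (0.355) by 0.164. Near and far pairs come from different genes, and a different spread of ratios among these genes can also change r. A part played by probe sequence cannot be told apart, since r was 0.663 even for probes up to 500 bp apart, some of which share sequence, and 0.605 for those that share none. Whether the higher ratio of the upstream probe comes from RNA breakage, from priming or from the bound mRNAs themselves was not tested.

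EIF4E mRNA had a low ratio of CBP80 IP over eIF4E IP (−2.14). Without an input or a dye swap, more of it in the eIF4E IP was not separated from less in the CBP80 IP or from a dye effect. An artefact of a single probe is argued against by the ratio of every EIF4E probe, at most −1.31 on either array. For recovery of the own target's mRNA by both antibodies, NCBP1 gave no sign at its 1 tested probe (−0.29, the 15.9th percentile of tested genes). The difference between probes of one gene had an SD of 0.50, so a single probe does not settle it. Whether mRNAs for eIF4E-binding proteins are recovered as a group cannot be told apart from chance, since the median of 9 such genes (−0.10) lay at the 18.9th percentile of 10000 random lists, with EIF4ENIF1 at −1.47 and EIF4EBP2 at 0.71. Recovery of EIF4E polysomes through nascent eIF4E by its antibody may be a candidate explanation and was not tested.

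Replication-dependent histone mRNAs and some small noncoding RNAs (5 of 33 by 2-fold) had high ratios toward the CBP80 IP. A GC bias of the histone probes is argued against by their median of 1.61 after the GC correction. A property of all histone genes is argued against by the median of −0.14 of the replication-independent ones. For a missing poly(A) tail, 7SK RNA and 18S rRNA had low ratios, at most −1.78 on either array. These RNAs were chosen after their ratios were seen, so they do not decide whether a missing tail plays a part. An effect of a missing tail on labelling was not separated from a difference in the amount of RNA. Of the 33 small structured noncoding RNAs, 23 were called higher in the CBP80 IP and 1, 7SK RNA, lower. Nuclear RNA carried into the CBP80 IP cannot be told apart, since the nuclear long noncoding RNA list had a median at percentile 94.1 of random lists. More RNA without a cap in the CBP80 IP stays open too, since the median of the mitochondrial probes was 1.14 while 18S rRNA went the opposite way. The small structured noncoding RNAs, RPPH1, RN7SL1 and RMRP among them, were not sorted by whether they carry a cap. Their high ratios thus do not show binding through a cap. Cross-hybridisation among the replication-dependent histone genes and a dye effect were not tested, and the design gives no second group for a biological explanation.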
